A study of Mus musculus with 3 samples.

How the data were processed

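Open chromatin was measured by single-cell ATAC-seq, in which the transposase Tn5 cuts accessible DNA and the ends of the resulting fragments are counted in each barcoded nucleus. Per the labels, mouse gliomas were dissociated, nuclei were extracted and libraries were made with the 10x Chromium Next GEM Single Cell ATAC v2 kit. There were 3 libraries, 1 each for overexpression of PDGFB-WT, overexpression of PDGFB-NLS and Control. All 3 carried the tissue label glioma, and the meaning of NLS was left as the labels give it. Groups were taken from the sample titles.

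The deposited matrices held, per the file headers, output of cellranger-atac 2.1.0. The submitters' processing notes name Cell Ranger 8 and the mouse build mm10. The deposited values were raw counts per peak and barcode, with no normalization. Even values far outnumbered odd ones, and the value 2 made up 72.9% of the entries in Control, 89.4% in PDGFB-WT and 87.9% in PDGFB-NLS. This is the pattern of cut sites, with both ends of a fragment in a peak counted as 2. A value v was read as (v + 1) // 2 fragments where fragments are named. Peaks were deposited as separate lists per library, so a region missing from a list was not called there and its count is unknown. The caller's settings and the rule for calling cells are not given in the sources used here.

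Barcodes with at least 200 counts were kept, and peaks on chromosomes 1 to 19, X and Y were used. This left 2226 of 2267 barcodes, 107627 peaks and 31588784 counts in Control. It left 7441 of 7511 barcodes, 57616 peaks and 7008951 counts in PDGFB-WT, and 10996 of 10996 barcodes, 127094 peaks and 31177621 counts in PDGFB-NLS. Overlapping peaks of the 3 lists were merged into 147229 regions, of which 47450 (32.2%) were called in all 3 libraries. Counts in those regions set the scale, as CPM, the count scaled to a total of 1000000 per library. They held 81.6% of the counts in Control, 96.3% in PDGFB-WT and 78.8% in PDGFB-NLS.

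Gene positions came from a RefSeq table of GRCm38.p6, the assembly of mm10, which gives no strand. The design had named windows around transcription start sites. In their place, counts were summed over peaks within 1000 bp of each end of a gene, and the end with the higher mean CPM over the 3 libraries was used. Of 21887 protein-coding genes, 12845 had such a peak in all 3 libraries. Where peaks lay at both ends (4563 genes), the lower end held a median of 0.16 of the CPM of the higher end. Genes with at least 100 counts in the library with fewer were compared, which gave 10722 genes for PDGFB-WT against Control, 12495 for PDGFB-NLS against Control and 10738 for PDGFB-NLS against PDGFB-WT. A gene's value was the log2 ratio of CPM, with an exact 95% interval (Clopper-Pearson on the conditional binomial, computed on fragments). The median of all compared genes was -0.16, -0.02 and 0.13 in these comparisons. All gene and list ratios over whole libraries are therefore given relative to that median.

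The choices made before the data were examined were the comparisons, the thresholds other than those for naming clusters, 13 gene lists, 12 cell type marker lists, and the alternatives unless stated. The gene lists were PDGF receptor signalling, chromosome segregation and spindle checkpoint, cohesin and condensin, DNA damage response and repair, p53 targets, DNA replication and cell cycle, chromatin regulators and IDH enzymes, hypoxia and glycolysis, interferon response, AP-1 and mesenchymal state, HOX genes, synapse genes, and ribosomal protein genes. The marker lists were those of oligodendrocyte precursor cells (OPC), oligodendrocytes, astrocytes, excitatory and inhibitory neurons, microglia or macrophages, lymphocytes, endothelial cells, mural cells or fibroblasts, neural progenitors, ependymal cells and erythroid cells. All symbols of 22 lists were found in the gene table, and 25 of 27 interferon, 17 of 18 lymphocyte and 11 of 12 erythroid symbols. A list with at least 5 compared genes was summarised by its median and by the percentile of that median among 10000 random lists of the same size, matched on mean CPM in 20 bins. A median below the 2.5 or above the 97.5 percentile was called outside the random range. The percentile describes these libraries and is no test between conditions. Named genes were the 7 with the highest and the 7 with the lowest ratio in each comparison, the 2 highest and 2 lowest members of each gene list, and Pdgfra, Pdgfrb, Olig2 and Sox10 where measured.

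Barcodes were clustered in each library alone. Peaks found in at least 1% of barcodes, read as open or not, were weighted by term frequency and inverse document frequency, reduced by singular value decomposition to components 2 to 30, joined to 15 neighbours and grouped by Leiden clustering at resolution 0.6. Activity of a gene was its count over the gene body plus 2 kb at both ends. A cluster took the name of the marker list with the highest median log2 fold over the other clusters if that median was at least 1 and at least 3 markers were raised 2-fold. These naming thresholds were set after the clusters had first been seen, and they left 6.92% of barcodes unnamed in Control, 23.3% in PDGFB-WT and 0 in PDGFB-NLS. Names read "X-like" and rest on open chromatin alone. A named class was compared between libraries only where none of its clusters had more markers of another class than of its own among its 10 leading genes. Control cluster 4 and PDGFB-WT cluster 3, both astrocyte-like, failed this, so astrocyte-like clusters were compared by number. Shares of barcodes have exact binomial intervals. Gene ratios within a class were computed from counts summed over its barcodes, for classes of at least 100 barcodes in both libraries. Doublets were called with Scrublet in Scanpy, which marked 8 barcodes in Control (0.36%), 0 in PDGFB-WT and 2028 in PDGFB-NLS (18.4%). The caller did not work in 2 of the libraries, so doublets were kept in all 3, where removal had been planned, and removal in PDGFB-NLS became an alternative.

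For each chromosome, the share of a library's counts over regions called in all 3 libraries was compared between libraries as a log2 ratio, with the spread of its 10 Mb bins. Such shares follow copy number and accessibility together. The cell-to-cell spread was the variance over barcodes of a chromosome's share, divided by the binomial variance, after each barcode was thinned to 500 counts on autosomes. The median over the 19 autosomes was taken.

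Every interval covers counting error only, except those over member genes or autosomes to which the alternatives of list medians and spreads were held. With 1 library per group, no p-value, standard error or count of changed genes was computed. The gene ratios were tested on simulated counts with the real depths, where all 14 genes at the extremes were among those changed and the intervals held the true ratio for 93% to 98% of changed genes. The counts were drawn from a mean shared by both libraries over fixed peaks. The simulation thus held counting error alone and cannot show how unequal peak lists or other differences between libraries move the named genes. Of 100 simulated lists without a shift, 5 fell outside the random range for PDGFB-WT against Control and 6 in each other comparison, and all 50 lists shifted by 0.5 lay above the 97.5 percentile. The unshifted lists were drawn at random from the same genes as the reference lists, so a share near this was set in advance. Neither kind of list shows how often a list of related genes leaves the range through differences between real libraries. Simulated barcodes without any gain gave a cell-to-cell spread of 1.08 at the depths of Control, 1.50 at those of PDGFB-WT and 1.26 at those of PDGFB-NLS in cut sites, and of 0.996, 1.00 and 0.993 in fragments.

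The alternatives covered the scaling, the window at gene ends, peak length, the count minimum, the barcode minimum, capping of counts to 0 or 1 per peak, the overlap rule and the peak threshold, the clustering resolution and components, doublets, thinning, and the regions used for chromosome shares. Others were added after seeing the data. These were both gene ends summed, genes with peaks at 1 end only, fragments, only regions called in all 3 libraries, a minimum of 20 within classes alone or with those regions or with capping, the OPC-like class at resolution 1.0, thinned or capped microglia-like barcodes with summed markers, and only named classes in the denominator. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, umap-learn 0.5.12, igraph 0.11.9, Scanpy 1.11.5 and Matplotlib 3.10.9. Sequence-level analyses were not done, and peaks on unplaced scaffolds entered no comparison.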

Results

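Chromatin accessibility was profiled in nuclei from a mouse glioma series made by in utero electroporation, in which piggyBac transposon plasmids are introduced into the embryonic brain. All libraries, Control included, carry the tissue label glioma, and whether Control is a tumor is not clear from the labels. The series title ties PDGFB, a growth factor that acts through the receptors PDGFRA and PDGFRB, to chromatin and to chromosome instability. The 3 libraries came from PDGFB-WT overexpression, PDGFB-NLS overexpression and Control, and the comparisons of the design were each PDGFB library against Control and PDGFB-NLS against PDGFB-WT. With 1 library per group, no difference had a replicate check, and intervals cover counting error within these libraries only. Control held 2226 barcodes with a median of 13054 counts (quartiles 5672.25 and 22420.5). PDGFB-WT held 7441 barcodes with a median of 821 counts (468 and 1252), and PDGFB-NLS held 10996 with a median of 2767.5 counts (1877 and 3664.5). Barcodes with at least 1000 counts made up 94.0% of Control, 38.8% of PDGFB-WT and 92.7% of PDGFB-NLS. Peaks covered 95.2 Mb in Control, 51.0 Mb in PDGFB-WT and 111 Mb in PDGFB-NLS, at a mean of 332, 137 and 281 counts per kb.

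Most open regions of PDGFB-WT were also called in the other libraries. Of its 57616 peaks, 84.2% (95% exact binomial interval 83.9% to 84.5%) overlapped a Control peak and 88.2% (87.9% to 88.4%) a PDGFB-NLS peak. Of the 127094 PDGFB-NLS peaks, 72.8% (72.5% to 73.0%) overlapped Control peaks and 40.1% (39.8% to 40.4%) overlapped PDGFB-WT peaks. The lists were called at unequal depth and differ in length. Among the 20000 peaks with most counts per kb in each library, 79.2% of those of PDGFB-WT and 88.1% of those of PDGFB-NLS overlapped such a Control peak. The share of counts within 1000 bp of a gene end, over regions called in all 3 libraries, was 58.7% in Control, 53.2% in PDGFB-WT and 57.5% in PDGFB-NLS.

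Cells resembling oligodendrocyte precursors (OPC), which carry the receptor PDGFRA, took a larger share of barcodes in both PDGFB libraries than in Control. The OPC-like share was 2.65% in Control (59 of 2226, 95% interval 2.02% to 3.41%), 27.7% in PDGFB-WT (2059 of 7441, 26.7% to 28.7%) and 13.7% in PDGFB-NLS (1506 of 10996, 13.1% to 14.4%). It was held by cluster 9 in Control, cluster 2 in PDGFB-WT and cluster 4 in PDGFB-NLS. Microglia or macrophage-like nuclei, the resident immune cells, made up 22.9% (21.2% to 24.7%), 30.9% (29.9% to 32.0%) and 25.6% (24.8% to 26.4%) in the same order, in cluster 1 of Control, cluster 1 of PDGFB-WT and cluster 2 of PDGFB-NLS. Oligodendrocyte-like nuclei, the myelinating type, held 15.8% of Control (14.3% to 17.4%; cluster 3) and 18.7% of PDGFB-NLS (18.02% to 19.5%; cluster 3). Endothelial-like nuclei of blood vessels held 22.4% of Control (20.7% to 24.2%; clusters 2 and 8) and 11.1% of PDGFB-NLS (10.5% to 11.7%; cluster 5). Neither class had a cluster of its own in PDGFB-WT.

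Inhibitory neuron-like barcodes made up 1.35% of Control (0.911% to 1.92%) and 4.87% of PDGFB-NLS (4.48% to 5.29%), but at resolution 1.0 they made up 8.45% and 3.10%, and in PDGFB-NLS no such cluster was named with doublets removed. Mural or fibroblast-like (5.97%, 5.03% to 7.04%) and lymphocyte-like (1.44%, 0.985% to 2.02%) clusters were found in Control alone, the library with the deepest barcodes. With Control barcodes thinned to 1000 counts, neither class was named there either (0 of 2093 barcodes), nor were inhibitory neuron-like ones. Their absence from the PDGFB libraries can therefore not be told apart from depth. Astrocyte-like clusters were compared by number only. They were clusters 4 and 5 in Control (11.95% and 8.67%), 3 in PDGFB-WT (18.1%) and 1 in PDGFB-NLS (25.96%). Clusters 4 (14.5%, median 380.5 counts) and 5 (8.76%, median 666 counts) of PDGFB-WT had no name. The median depth of the OPC-like clusters was 12825 counts in Control, 1000 in PDGFB-WT and 3148.5 in PDGFB-NLS. Each library was clustered alone, and with 1 library per group a difference in class shares cannot be told apart from a difference between libraries. At resolution 1.0 PDGFB-WT held 20.4% OPC-like and 9.93% oligodendrocyte-like barcodes. How many of these had lain in its OPC-like cluster was not traced. Control barcodes thinned to 1000 counts gave no OPC-like cluster. At resolution 0.3 none of the 3 PDGFB-WT clusters had a name, so no class of any kind was found there.

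**Figure D1:**
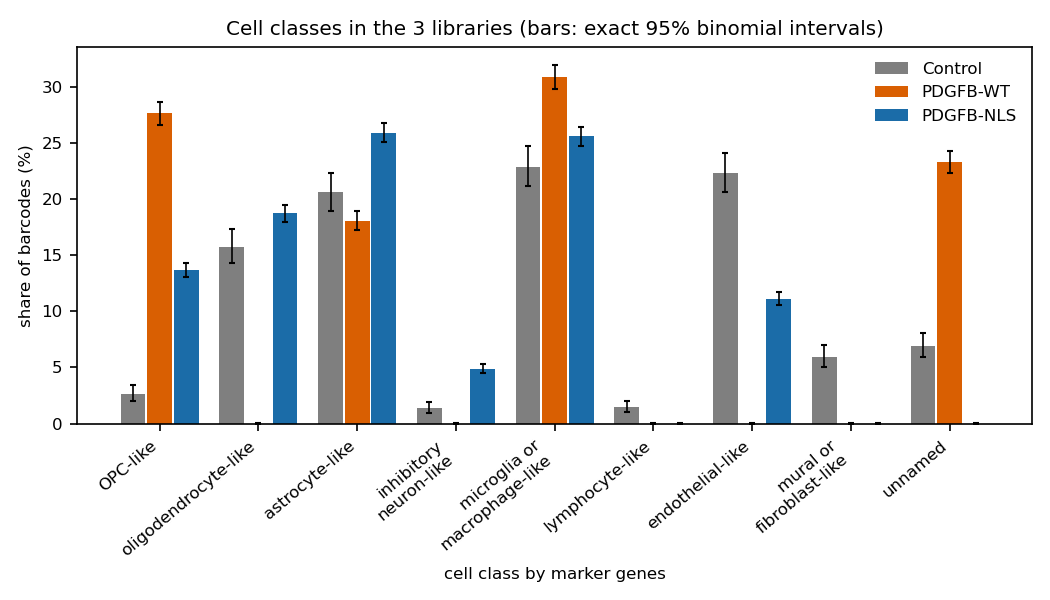
Share of barcodes (percent, y axis) in each class for Control, PDGFB-WT and PDGFB-NLS, with exact 95% binomial intervals as error bars that cover counting error within 1 library each. OPC-like barcodes made up 2.65%, 27.7% and 13.7%, and astrocyte-like bars are shown although that class was compared by cluster number only.

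In PDGFB-WT, the measured gene ends of astrocyte, OPC and neural progenitor markers (11 of 18 in each list) were more accessible than in Control. Astrocyte markers stood 0.75 above the all-gene median on the log2 scale (9 of 11 measured genes above it, percentile 99.84 among matched random lists). Neural progenitor markers stood at 0.62 (9 of 11, percentile 99.995) and OPC markers at 0.50 (9 of 11, percentile 99.16). Hypoxia and glycolysis genes lay below the median at -0.24 (4 of 17 above it, percentile 0.18), as did chromosome segregation and spindle checkpoint genes at -0.17 (9 of 25 above it, percentile 1.35). Of 17 lists with enough measured genes, these 5 left the random range. The 100-count minimum fell unequally, with 7008951 counts in PDGFB-WT and 31588784 in Control. Genes high in PDGFB-WT and low in Control passed it more readily than the reverse, which also bears on the single genes below. The astrocyte, OPC and progenitor calls held with no minimum, which still needs a peak in PDGFB-WT. How far this raised the medians was not tested. The call ended under 5 of 14 alternatives for segregation genes, 4 of 14 for hypoxia genes and 1 of 13 each for OPC and progenitor markers. Among the alternatives here and below are the all-gene median set to 0 and the scale taken over all own peaks. Both move every ratio of a comparison alike, so a call could hardly end under them. The ranges of medians given here and below include both. Before the all-gene median was taken off, the medians under these alternatives ran from 0.07 to 1.15 for OPC markers (0.34 in the main setting), 0.03 to 0.70 for progenitor markers (0.46), 0.40 to 0.83 for astrocyte markers (0.59), -0.47 to -0.16 for hypoxia genes (-0.40) and -0.35 to -0.09 for segregation genes (-0.33).

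The gene ends with the highest ratios in PDGFB-WT included Scrg1, the scrapie-responsive gene (chromosome 8, 57455882 to 57479360, mm10), at 37.6 CPM against 3.995 CPM in Control, a log2 ratio of 3.39 above the all-gene median (2.93 to 3.87), or 10.5-fold. Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102897200), was 8.08-fold higher (log2 3.01, 2.60 to 3.44). The transcription factor genes Sox11 (chromosome 12, 27334268 to 27342718) and Nr2f2 (chromosome 7, 70351946 to 70366746) were higher by 2.41 (2.01 to 2.81) and 2.48 (1.97 to 2.99). Dnah9, an axonemal dynein heavy chain (chromosome 11, 65831324 to 66168581), was higher by 2.43 (1.959 to 2.90). These 5 of the 7 highest genes kept over 2 parts in 3 of their ratio in regions called in all 3 libraries. Among the 7 lowest, 3 did so. They were Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462675; -1.92, -2.12 to -1.73), the retinol dehydrogenase gene Rdh10 (chromosome 1, 16105882 to 16132550; -1.74, -2.05 to -1.44) and Glo1, glyoxalase 1 (chromosome 17, 30592861 to 30612659; -1.71, -1.97 to -1.47). The common region of Rdh10 is also that of the ribosomal protein gene Rpl7. The ratios of Myt1l, H3c4, Gm10277, Adgrb2, Stat5b and Fam89b did not hold in the common regions, or the gene had none there.

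Among the segregation genes, Pttg1 (securin; -0.52, -0.88 to -0.17) and the checkpoint kinase gene Bub1 (-0.51, -0.86 to -0.19) were lowest, while Nuf2 (0.51, 0.27 to 0.74) and Mad2l1 (0.25, 0.09 to 0.42) were highest. Of the hypoxia genes, Ndrg1 (-0.90, -1.20 to -0.61) and Bnip3 (-0.72, -0.99 to -0.46) were lowest, and the oxygen sensor Egln1 (0.55, 0.27 to 0.82) and P4ha1 (0.22, 0.07 to 0.38) were highest. PDGF receptor signalling genes stayed inside the random range, with a median of -0.05 (7 of 22 above the all-gene median). Its extremes were the ligand genes Pdgfb (-0.63, -0.98 to -0.30) and Pdgfc (0.27, -0.10 to 0.63), the feedback inhibitor Spry2 (0.33, 0.10 to 0.56) and the kinase gene Mapk3 (-0.52, -0.75 to -0.29), of which Mapk3 was at 0.17 in the common regions. Olig2 was at 0.14 (-0.19 to 0.47) and Sox10 at 0.50 (0.11 to 0.88). Pdgfra and Pdgfrb fell short of 100 counts in PDGFB-WT.

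Other lists of this comparison stayed inside the range. Cohesin and condensin genes had a median of -0.09, with Ncapd3 (0.85, 0.66 to 1.03) and Smc1a (0.25) highest and Smc2 (-0.34) and Mau2 (-0.33) lowest. DNA damage genes were at -0.06 (Chek1 0.51, Xrcc5 0.43, Msh6 -0.54, Chek2 -0.53) and p53 targets at -0.07 (Phlda3 0.35, Sesn2 0.14, Pmaip1 -0.39, Bbc3 -0.37). Replication and cell cycle genes were at -0.07 (Ccnd1 0.70, Cdkn2b 0.23, Cdk2 -0.58, Cdt1 -0.46). Chromatin regulators were at -0.01, where Eed (0.58) and Kmt2a (0.41) were highest and Arid1a (-0.36) and the dioxygenase gene Tet3 (-1.05) lowest. Per kb of peak length Tet3 was at 0.21 before the all-gene median was taken off. Interferon genes were at -0.13 (Ifit2 0.56, Irf9 0.08, Oasl1 -0.65, Bst2 -0.59), AP-1 and mesenchymal genes at 0.13 (Chil1 1.33, Atf3 -0.34, Tgfb1 -0.31), synapse genes at 0.34 (Snap25 1.28, Vamp2 -0.15, Shank1 -0.12) and ribosomal protein genes at 0.07 (Rpl5 0.46, Rps23 0.35, Rpl4 -0.46, Rpl13 -0.32). Microglia markers were at -0.22 over 7 genes and ependymal markers at -0.09 over 7. In the HOX list, Hoxa9 (0.31) and Hoxc10 (-0.14) were measured.

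**Figure D2:**
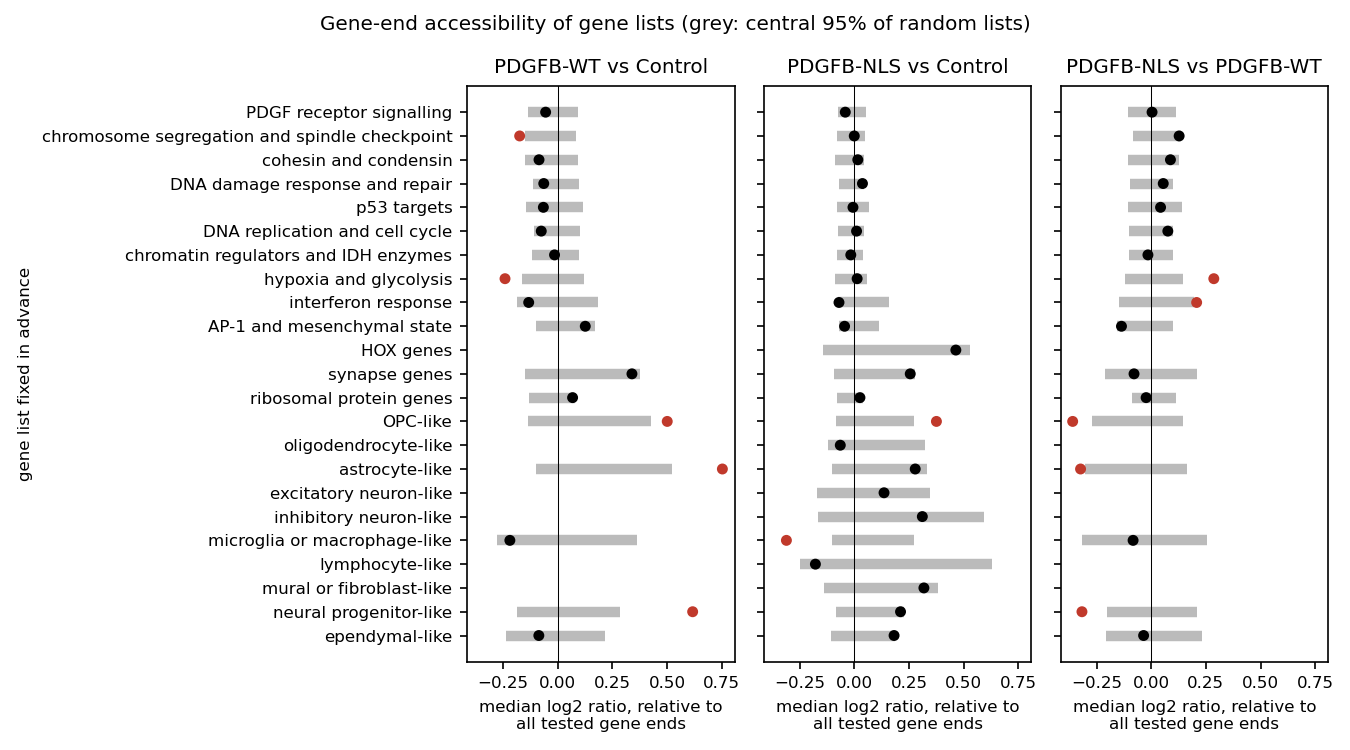
Median log2 ratio of each gene list relative to the median of all compared genes (x axis), in 3 panels for the 3 comparisons, with gray bars for the central 95% of matched random lists. In PDGFB-WT against Control the astrocyte (0.75), progenitor (0.62) and OPC (0.50) medians lie right of the bars and the hypoxia (-0.24) and chromosome segregation (-0.17) medians left of them.

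In PDGFB-NLS, OPC markers were also above Control, and microglia markers were below it. The OPC median lay 0.37 above the all-gene median (13 of 15 genes above it, percentile 99.6). The microglia or macrophage median lay at -0.31 (2 of 13 above it, percentile 0). The share of microglia-like barcodes was 25.6% here and 22.9% in Control, but the ratios sum counts, which deep barcodes dominate. Microglia-like barcodes had a median of 23288 counts in Control, against 13054 over all its barcodes. In PDGFB-NLS the medians were 3424.5 and 2767.5, so makeup by counts may lower these markers, which was not tested. The OPC and microglia lists were the 2 of 23 outside the random range. With counts capped to 0 or 1 per peak the microglia median was inside it, and with a minimum of 300 counts the OPC median was. Before the all-gene median was taken off, the OPC median ran from 0.12 to 0.52 over the alternatives (0.36 in the main setting) and the microglia median from -0.38 to -0.16 (-0.33).

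Gfap was the highest gene end at 5.89-fold (log2 2.56, 2.20 to 2.94), and Sox11 was 4.26-fold higher (2.09, 1.77 to 2.43). These 2 of the 7 highest kept over 2 parts in 3 of the ratio in the common regions. Scrg1, at 2.37 (1.95 to 2.82), was at 1.55 there. The ratios of H3c4 and Cnfn did not hold, Naa50 and Atp6v1a share 1 peak outside the common regions, and none held among the 7 lowest genes, Bsn, Stat5b, Crlf2, Uba7, Parp9, Klf10 and Dlx2. Pdgfra, the receptor gene used by OPC, was at 0.56 (0.17 to 0.96) and Pdgfrb, the receptor gene of mural cells, at 0.33 (-0.00 to 0.66). Olig2 (-0.01, -0.23 to 0.20) and Sox10 (0.04, -0.23 to 0.31) lay at the all-gene median.

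PDGF receptor signalling genes had a median of -0.04 (8 of 25 above the all-gene median), with Pdgfc (-0.59; 0.02 in the common regions) and Pdgfb (-0.44, -0.63 to -0.25) lowest. Chromosome segregation genes were at -0.00 (12 of 25), from Pttg1 (-0.27, -0.47 to -0.07) and Birc5 (-0.09) to Zwint (0.16) and the mitotic kinase gene Plk1 (0.27, 0.04 to 0.51). Cohesin and condensin genes were at 0.02 (Hdac8 0.27, Ncapd2 0.15, Pds5a -0.48, Pds5b -0.08) and DNA damage genes at 0.04 (Fancd2 0.35, Brca2 0.21, Atrx -0.73, Mdc1 -0.11), where Pds5a was at -0.13 and Atrx at -0.27 in the common regions. p53 targets were at -0.01 (Eda2r 0.28, Phlda3 0.24, Mdm2 -0.27, Btg2 -0.22). Replication and cell cycle genes were at 0.01, led by the locus of the cell cycle inhibitors Cdkn2a (0.67, 0.45 to 0.89) and Cdkn2b (0.17), with Rb1 (-0.29) and Cdk2 (-0.22) lowest. Chromatin regulators were at -0.02, with the Polycomb gene Eed at 0.54 (0.40 to 0.67), Hdac2 at 0.42, Kdm6b at -0.33 and Tet3 at -0.65. In the common regions Hdac2 was at 0.09, Kdm6b at -0.08 and Tet3 at -0.02. Hypoxia genes were at 0.01 (Hk2 0.35, P4ha2 0.29, Ndrg1 -0.38, Bnip3 -0.27).

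Interferon genes stood at -0.07 (percentile 2.96), from Ifit1 (-0.62) and Sting1 (-0.26) to Tap1 (0.21) and Irf7 (0.79; 0.23 in the common regions). AP-1 and mesenchymal genes were at -0.04, with the matrix gene Tnc (1.14, 0.69 to 1.60) and Chil1 (0.56) highest and Atf3 (-0.28) and Tgfb1 (-0.22) lowest. HOX genes were at 0.46 over 8 genes (Hoxa4 0.78, Hoxd13 0.71, Hoxb8 0.05, Hoxc10 -0.40) and synapse genes at 0.26 over 15 (Syt1 1.34, Grin1 1.24, Shank1 -0.23, Syp -0.27), while in 2000 bp windows Grin1 was at -0.33 before the all-gene median was taken off. Ribosomal protein genes were at 0.03 (Rps6 0.19, Rpl5 0.17, Rps4x -0.16, Rpl18 -0.17). Among the cell type lists, the medians were 0.28 for astrocyte, 0.21 for progenitor, 0.18 for ependymal, 0.32 for mural or fibroblast, 0.31 for inhibitory neuron, 0.14 for excitatory neuron, -0.06 for oligodendrocyte and -0.18 for lymphocyte markers. Endothelial (4) and erythroid (3) markers were too few for a median.

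Set against PDGFB-WT, PDGFB-NLS showed more accessible hypoxia and interferon genes and less accessible OPC, astrocyte and progenitor genes. The hypoxia median was 0.29 (13 of 17 genes above the all-gene median, percentile 100) and the interferon median 0.21 (10 of 14, percentile 98.27). OPC markers were at -0.36 (3 of 13 above, percentile 0.53), astrocyte markers at -0.32 (1 of 11, percentile 1.62) and progenitor markers at -0.32 (2 of 11, percentile 0.185). These were 5 of 17 lists. The same PDGFB-WT library enters here and in its comparison with Control. Against Control, hypoxia genes stood at 0.01 in PDGFB-NLS and -0.24 in PDGFB-WT, and interferon genes at -0.07 and -0.13. Neither list was above the random range in PDGFB-NLS against Control. OPC (0.37 and 0.50), astrocyte (0.28 and 0.75) and progenitor (0.21 and 0.62) markers stood above the all-gene median in both. Here too the 100-count minimum bore more on PDGFB-WT. The call ended under 7 of 14 alternatives for interferon genes, 4 of 14 for hypoxia genes, 2 of 13 for progenitor, 1 of 13 for OPC and 1 of 12 for astrocyte markers. Before the all-gene median was taken off, the medians ran from 0.05 to 0.39 for interferon (0.34 in the main setting), 0.12 to 0.49 for hypoxia (0.41), -0.52 to -0.05 for OPC (-0.23) and -0.48 to -0.09 for astrocyte genes (-0.20). Over gene bodies the progenitor median was 0.02 on that scale, against -0.19 in the main setting.

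Rdh10 (3.93-fold, log2 1.98, 1.68 to 2.29), Glo1 (3.15-fold, 1.66, 1.41 to 1.91), Lars2 (2.97-fold, 1.57, 1.37 to 1.77), and the homeobox repressor gene Tgif2 (1.42, 1.03 to 1.83) were the 4 of the 7 highest that held in the common regions. The tetraspanin gene Cd151 (1.31, 0.92 to 1.72), which shares its gene end with Cracr2b, was at 0.86 there. Before the all-gene median was taken off, 5 of the 7 highest kept over 2 parts in 3 of their ratio. Rdh10, Glo1 and Lars2 had also been low in PDGFB-WT against Control, and the same PDGFB-WT library enters both comparisons. The 3 of the 7 lowest that held were Tmsb4x, the actin-binding thymosin beta 4 (3.13-fold lower, -1.65, -2.15 to -1.14), the thyroid hormone deiodinase gene Dio2 (2.94-fold lower, -1.56, -2.01 to -1.10) and the epoxide hydrolase gene Ephx2 (2.88-fold lower, -1.53, -1.88 to -1.17). Chosen by the same rule, Basp1, Mob3b, Cspg4, Parp9, Gm42517 and Ryr3 did not hold or had no common region, and over gene bodies Tmsb4x was at 0.13 before the all-gene median was taken off.

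Hilpda (0.66, 0.35 to 0.97) and Ndrg1 (0.53, 0.24 to 0.83) were the highest hypoxia genes, and Egln1 (-0.41, -0.68 to -0.13) and Vegfa (-0.23, -0.52 to 0.06) the lowest. Of the interferon genes, Oasl1 (0.59) and Psmb8 (0.39) were highest and Ifit2 (-0.68) and Gbp3 (-0.23; -0.01 in the common regions) lowest. Chromosome segregation genes stood at 0.13 (19 of 25 above, percentile 96.6), inside the random range, with Bub1 (0.52, 0.19 to 0.86) and the centromere histone gene Cenpa (0.47, 0.20 to 0.75) highest and Nuf2 (-0.51) and Mad2l1 (-0.25) lowest. PDGF receptor signalling genes were at 0.00 (Mapk3 0.36, Ptpn11 0.25, Pdgfc -0.85, Dusp6 -0.29), of which Mapk3 was at -0.26 in the common regions and Pdgfc had none there, with Olig2 at -0.15 (-0.47 to 0.20) and Sox10 at -0.45 (-0.83 to -0.06). Cohesin genes were at 0.09 (Mau2 0.33, Smc2 0.32, Stag2 -0.26, Ncapd3 -0.85), DNA damage genes at 0.06 (Chek2 0.51, Msh6 0.44, Chek1 -0.33, Atrx -0.58, the last at -0.11 in the common regions), p53 targets at 0.04 (Pmaip1 0.47, Bbc3 0.35, Sesn2 -0.18, Ei24 -0.19) and cell cycle genes at 0.08 (Cdkn2a 0.63, Cdt1 0.50, Cdk4 -0.19, Ccnd1 -0.57). Chromatin regulators were at -0.01 (Ezh2 0.56, Tet3 0.41, Smarca4 -0.36, Kmt2a -0.44; in the common regions Ezh2 0.21 and Tet3 1.05), AP-1 genes at -0.14 (Tgfb1 0.11, Cebpb 0.08, Bhlhe40 -0.46, Chil1 -0.76), synapse genes at -0.08 (Vamp2 0.10, Rab3a 0.05, Syp -0.92) and ribosomal protein genes at -0.02 (Rpl4 0.54, Rpl11 0.43, Rps4x -0.26, Rpl5 -0.28). Microglia markers were at -0.08 and ependymal markers at -0.03.

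Whole-library ratios mix the makeup of the cells with differences inside a class, so the lists were also read within classes. In the microglia-like class (2816 PDGFB-NLS against 510 Control barcodes, 10463 genes), microglia markers were lower in PDGFB-NLS at a median of -0.20 (3 of 13 above 0, percentile 0.03). AP-1 and mesenchymal genes were lower at -0.10 (percentile 2.02) and HOX genes higher at 0.34 (5 of 6 above 0, percentile 99.57), and the other 12 of 15 lists lay inside the random range. In PDGFB-WT microglia-like barcodes (2301) against Control, 0 of 12 lists left the range. A count minimum of 20, added after seeing the data, brought 3 of 19 lists outside it, with microglia markers at -0.37 (percentile 0.49), interferon genes at -0.26 and hypoxia genes at -0.19. With capped counts these hypoxia (-0.18, percentile 6.14) and interferon (-0.31, percentile 4.15) medians were inside it. In PDGFB-NLS against Control the same minimum brought 5 of 22 lists outside it, the 3 above with hypoxia genes, here higher at 0.10 (percentile 97.67), and synapse genes at -0.20 (percentile 2.03), the last inside it with capped counts (-0.30, percentile 6.55). Between the PDGFB libraries 0 of 12 lists left the range in this class, and at the minimum of 20 interferon genes were higher in PDGFB-NLS (0.31, percentile 99.44). The microglia marker calls ended when counts were capped to 0 or 1, with medians of -0.27 in PDGFB-WT and -0.12 in PDGFB-NLS, and the AP-1 median in PDGFB-NLS was then 0.07. The HOX median was 0.27 (percentile 94.77, inside the range) in the common regions at the minimum of 20.

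Within the OPC-like class, PDGFB-NLS (1506 barcodes) and PDGFB-WT (2059) differed in 0 of 12 lists. Oligodendrocyte-like barcodes of PDGFB-NLS (2061) and Control (351) differed in 0 of 15 lists. At the minimum of 20, 1 of 20 lists left the range there, AP-1 genes at -0.11 (percentile 2.37), and with common regions as well 2 of 20, AP-1 genes at -0.15 (percentile 1.57) and PDGF receptor signalling genes at -0.25 (3 of 21 above 0, percentile 0.47). In endothelial-like barcodes (1223 and 498) chromatin regulators were higher at 0.08 (percentile 97.98), the 1 of 11 lists outside the range. At the minimum of 20 they were at 0.05 (percentile 91.6), inside it, and at -0.02 with capped counts as well. PDGFB-NLS cluster 1 against Control cluster 5, both astrocyte-like, gave 0 of 13 PDGF receptor signalling genes above 0 (median -0.39, percentile 1.01) and a progenitor marker median of -0.49 (percentile 0.46), where the all-gene median was -0.22. That progenitor median was inside the range at the minimum of 20 (-0.09, percentile 31.33), and at 0.09 with capped counts as well. Against Control cluster 4, OPC markers were at -0.39 over 5 genes (percentile 2.06). At the minimum of 20, 4 of 19 lists were outside the range against cluster 5, where PDGF receptor signalling (-0.32), HOX (-0.36), OPC (-0.33) and astrocyte genes (-0.29) were lower, and 4 of 20 against cluster 4, where hypoxia genes were higher (0.23) and OPC (-0.31), excitatory (-0.32) and inhibitory neuron markers (-0.48) lower. Of these, the OPC median (-0.23) against cluster 5 and the hypoxia (0.15) and excitatory neuron (-0.30) medians against cluster 4 were inside the range with capped counts. In the common regions the astrocyte median against cluster 5 (-0.24) and the excitatory (-0.20) and inhibitory neuron (-0.04) medians against cluster 4 were inside it. In PDGFB-WT cluster 3 against Control clusters 4 and 5, and in PDGFB-NLS cluster 1 against PDGFB-WT cluster 3, 0 of 10 lists were outside it. At the minimum of 20 there were 2, 2 and 1 of 18, with all-gene medians of -0.12, -0.19 and 0.16. In clusters 3 and 4, segregation genes were at -0.38 (7 of 25 above 0, percentile 0.64), with 0.10 over 7 genes in the main setting, and synapse genes at -0.49 (percentile 0.265). In clusters 3 and 5, interferon genes were at 0.48 and OPC markers at -0.52 (percentile 0.48), and between the PDGFB libraries synapse genes were at 0.42 (percentile 98.72). With capped counts the segregation (-0.23), interferon (0.33) and OPC (-0.41) medians were inside the range, as were the interferon (0.36) and, between the PDGFB libraries, synapse (0.21) medians in the common regions.

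Over whole libraries, no chromosome reached the shift that an extra copy in every cell would give, 0.58 on the log2 scale, or that of a lost copy, -1. The libraries mix cell classes, microglia-like barcodes among them. A gain or loss in part of the cells would move a share less, so these bars cannot exclude it. Chromosome 17 had the largest ratio of the autosomes in each comparison, with the share of counts lower than in Control by -0.19 in PDGFB-WT and -0.10 in PDGFB-NLS. Its 10 Mb bins had medians of -0.00 and 0.00 with SDs of 0.32 and 0.14, and the bin from 30000001 to 40000000 stood at -0.60 and -0.34. Between the PDGFB libraries the share of chromosome 17 was higher in PDGFB-NLS by 0.09. In distal regions chromosome 17 stood at -0.41, -0.22 and 0.19 in the 3 comparisons, and in the microglia-like class at -0.31, -0.15 and 0.16. Without the 475 regions with most counts (1%), chromosome 17 stood at -0.07, -0.02 and 0.05, and the largest autosomal ratios were those of chromosomes 13 (0.08), 18 (0.02) and 14 (-0.07). The share of chromosome X was lower in PDGFB-NLS than in PDGFB-WT by -0.13, with a bin median of -0.10, which exceeded the ratio of chromosome 17 there. A simulated gain of chromosome 7 in 20% of barcodes moved its share by 0.11 to 0.12.

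**Figure D3:**
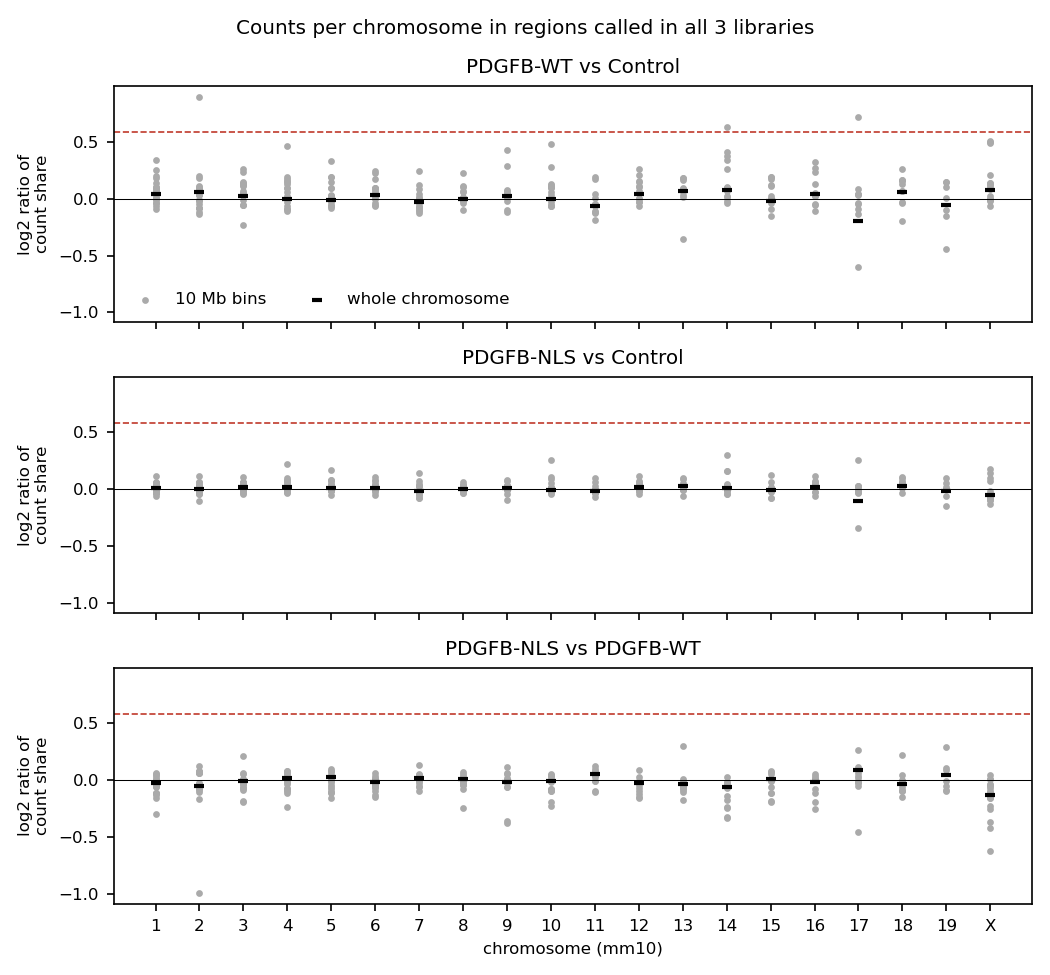
Log2 ratio of the share of counts (y axis) for each chromosome (x axis) in 3 panels for the 3 comparisons, with black bars for whole chromosomes, gray points for 10 Mb bins and a dashed line at 0.58, the value of 1 extra copy in every cell. Chromosome 17 is lowest at -0.19 and -0.10 in the comparisons with Control.

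Cell-to-cell spread of chromosome shares was highest in Control and lowest in PDGFB-NLS. At 500 cut sites per barcode the median over autosomes was 2.04 times the binomial variance in Control (2131 barcodes, range 1.62 to 3.10 over chromosomes), 1.77 in PDGFB-WT (5206 barcodes, 1.64 to 2.43) and 1.40 in PDGFB-NLS (10706 barcodes, 1.35 to 1.67). Counted as 250 fragments, an alternative added after seeing the data, the values were 1.51, 1.15 and 1.06. Within the microglia-like class in fragments they were 0.995 in Control, 1.05 in PDGFB-WT and 1.002 in PDGFB-NLS, and within the OPC-like class 1.21, 1.05 and 1.03. Endothelial-like barcodes gave 1.35 in Control and 1.18 in PDGFB-NLS, and mural or fibroblast-like barcodes of Control 1.56. Oligodendrocyte-like barcodes gave 0.989 in Control and 1.01 in PDGFB-NLS. Astrocyte-like barcodes gave 1.06 in Control, 1.08 in PDGFB-WT and 1.09 in PDGFB-NLS. A simulated gain of chromosome 7 in 20% of barcodes raised the spread of that chromosome in fragments to between 1.58 and 1.67. Thinning left out 95 barcodes of Control, 2235 of PDGFB-WT and 290 of PDGFB-NLS.

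**Figure D4:**
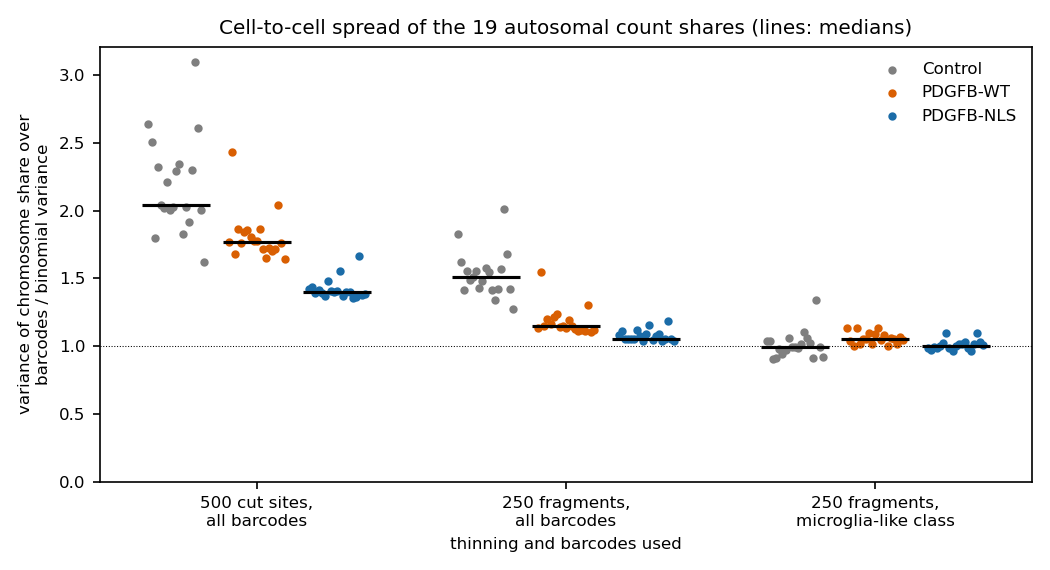
Variance over barcodes of each autosome's share divided by the binomial variance (y axis), with 1 point per autosome for Control, PDGFB-WT and PDGFB-NLS, at 500 cut sites, at 250 fragments and at 250 fragments within the microglia-like class. The medians were 2.04, 1.77 and 1.40 in cut sites and 0.995, 1.05 and 1.002 within the class.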

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

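The tests on the OPC-like share, the tests of other cell types' counts and of macrophages in the microglia-like class and the comparisons of summed markers were chosen after the results were seen.

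Interferon genes in PDGFB-WT against Control had a median log2 ratio of 0.48 in cluster 3 of PDGFB-WT against cluster 5 of Control (7 genes, percentile 97.79), clusters compared by number because cluster 3 failed the rule for comparing a class, and -0.26 in the microglia-like class (19 genes, percentile 2.09). The medians, at a minimum of 20 counts added after seeing the data, differed by 0.75, and the difference was not tested. The call in clusters 3 and 5 was lost in regions called in all 3 libraries (0.36, percentile 93.73) and with capped counts (0.33, percentile 97.03), and that in the microglia-like class was lost with capped counts (-0.31, percentile 4.15). HOX genes in PDGFB-NLS against Control had a median of 0.34 in the microglia-like class (8 genes, percentile 97.79) and -0.36 in clusters 1 and 5, both astrocyte-like (6 genes, percentile 1.3). They differed by 0.71, also untested, and the call in the microglia-like class was lost in regions called in all 3 libraries (0.27, percentile 94.77). Counts on unplaced scaffolds, which entered no comparison, made up 0.139% of PDGFB-WT (lower bound 0.135%) and 0.103% of Control (upper bound 0.104%), with 51.0 and 95.2 Mb covered by peaks at a mean of 137 and 332 counts per kb.

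OPC-like barcodes took the largest share in PDGFB-WT and the smallest in Control. With barcodes thinned to 1000 counts the shares were 32.6% in PDGFB-WT and 15.3% in PDGFB-NLS, a gap of 17.3 percentage points. Counts per barcode were equal there, but thinning kept 2889 of 7441 PDGFB-WT barcodes and 10195 of 10996 of PDGFB-NLS. It named no oligodendrocyte-like class in PDGFB-WT, against 21.7% in PDGFB-NLS. Depth therefore cannot be told apart for PDGFB-WT over PDGFB-NLS across whole libraries. Control gave no OPC-like cluster at that depth, so its place stays open too. Oligodendrocyte-like barcodes inside the PDGFB-WT cluster were argued against as the whole cause. At resolution 1.0, which named an oligodendrocyte-like class in PDGFB-WT, 20.4% were OPC-like, above the upper bound of 12.6% for PDGFB-NLS. Barcodes were not traced between resolutions. The form of PDGFB may set the shares, but with 1 library per group it cannot be told apart from any other difference between the libraries.

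Cell-to-cell spread of chromosome shares was highest in Control and lowest in PDGFB-NLS. Pairing of cut sites was argued against as the whole cause, since the range was 0.646 in cut sites and still 0.456 in fragments. Different mixtures of cell classes are a candidate explanation, as the range within the microglia-like class was 0.0594, and in fragments Control was lowest among oligodendrocyte-like barcodes (0.989 against 1.01 in PDGFB-NLS). Control was also lowest among astrocyte-like barcodes (1.06 against 1.08 in PDGFB-WT and 1.09 in PDGFB-NLS), although those clusters failed the rule for comparing a class. Control stayed higher within the OPC-like class (1.21 from 59 barcodes, against 1.05 and 1.03) and the endothelial-like class (1.35 against 1.18 in PDGFB-NLS). In these 2 classes, mixtures by these names leave part of it open. A difference in chromosome copy number between the groups was not tested apart from these.

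Microglia markers were lower within the microglia-like class of both PDGFB libraries than of Control, and both comparisons share the Control library. A larger part of macrophages was argued against in PDGFB-NLS, where markers of microglia proper (0.06) lay 0.274 above pan-myeloid ones (-0.22) and their summed ratios parted (-0.11 to 0.15 against -0.33 to -0.16), and cannot be told apart in PDGFB-WT, where they differed by 0.29 (-0.10 and -0.39) but the intervals of the sums overlapped (-0.26 to 0.16 against -0.52 to -0.23) and P2ry12, a marker of microglia proper, was at -0.88. Counts of other cell types cannot be told apart for both comparisons together, because these part. The needed ratio was that for the smallest fall in the interval of the microglia marker sum, -0.16 in PDGFB-WT and -0.10 in PDGFB-NLS. The falls of the sums themselves would need more. In PDGFB-WT the summed markers of other types were at 0.00 (-0.12 to 0.13), short of the needed 0.16 even at the upper bound. In PDGFB-NLS they were at 0.16 (0.09 to 0.24), where 0.11 was needed (needed ratio minus upper bound, -0.136). The sums cover only gene ends with a peak in all 3 libraries. Gene activity of the class against the other clusters of its library put endothelial markers at 0.25 in PDGFB-WT and -1.66 in Control. Oligodendrocyte markers were at -0.67 and -3.19, astrocyte markers at -1.77 and -1.60, and OPC markers at -2.20 and -2.16. The other clusters differ between the libraries, so counts of other types stay open in PDGFB-WT as well. Depth cannot be told apart either, because at 500 counts per barcode 2 microglia markers had 20 counts where the median needs 5. Summed over 13 markers, the ratios were -0.28 (-0.40 to -0.16) in PDGFB-WT and -0.17 (-0.24 to -0.10) in PDGFB-NLS with all counts, -0.26 (-0.38 to -0.14) and -0.13 (-0.21 to -0.06) with counts capped to 0 or 1, -0.24 (-0.60 to 0.14) and -0.13 (-0.48 to 0.24) at 250 fragments per barcode, and -0.20 (-0.47 to 0.09) and -0.00 (-0.26 to 0.26) at 500 counts and capped; both thinned settings hold 0 and the values with all counts in their intervals.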

How the results depend on the processing

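The alternatives with fragments, a minimum of 20, regions called in all 3 libraries and named classes alone were added after the data were seen. Removal of doublets had been the planned main choice and became an alternative, in PDGFB-NLS alone, once the caller's output was seen. No paired analysis was possible because each group had 1 library. Of the alternative values, those that kept within the counting interval numbered 60 of 107 for class shares, 2265 of 2565 for named genes, 5 of 18 for chromosome profiles and 0 of 18 for peak overlaps. List medians were held to an interval of the median over member genes, and spreads to one over the 19 autosomes. These follow scatter between genes or chromosomes, not counting error. Within them stayed 724 of 771 list medians, 551 of 589 medians within classes and 2 of 19 spreads. The cause was not tested except where stated. Depth limits PDGFB-WT most, with a median of 821 counts per barcode.

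The OPC-like share of PDGFB-WT was 20.4% at resolution 1.0, 31.6% in barcodes with at least 1000 counts, 32.6% with barcodes thinned to 1000 counts and 36.1% of named classes, the last by its smaller denominator. PDGFB-WT at resolution 0.3 had no named class of any kind, and thinned Control gave no OPC-like class. In PDGFB-NLS it was 14.36% at resolution 0.3, 11.99% at 1.0, 14.44% in barcodes with at least 1000 counts, 15.3% thinned and 11.4% with doublets removed.

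With an overlap of 50% of the shorter peak, a minimum of 20 CPM and the 20000 peaks with most counts per kb, 83.7%, 78.6% and 79.2% of PDGFB-WT peaks overlapped Control. The same settings gave 72.4%, 94.3% and 88.1% for PDGFB-NLS with Control, and 39.8%, 95.2% and 83.6% for PDGFB-NLS with PDGFB-WT.

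The largest autosomal ratio of PDGFB-WT against Control was 0.078 without 1% of regions, -0.41 in distal regions, -0.31 in the microglia-like class, -0.21 in barcodes with at least 1000 counts and -0.15 over all own peaks. For PDGFB-NLS against Control it was 0.023, -0.22 and -0.15 in the first 3 settings. For PDGFB-NLS against PDGFB-WT it was -0.067, 0.19, 0.16, 0.11 and 0.049 in all 5.

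The spread of Control was 2.92 at 1000 counts, 1.04 in the microglia-like class, 1.695 capped to 0 or 1, 1.51 at 250 fragments and 0.995 in fragments within that class. PDGFB-WT gave 1.88, 1.62, 1.06, 1.15 and 1.05 in the same settings, and PDGFB-NLS 1.65, 1.22, 1.05, 1.06 and 1.002, with 1.63 in distal regions and 1.43 with doublets removed.

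Among all raw log2 ratios, called or not, the sign changed in 20 of 57 list medians with the scale taken over all peaks of the own library, 10 with the all-gene median set to 0 and 9 per kb of peak. It changed in 25 of 200 named genes per kb, 25 of 200 over gene bodies and 7 of 189 in common regions. The following are those among lists outside the random range and named genes with a log2 ratio of at least 1 in size and an interval clear of 0. The progenitor median of PDGFB-NLS against PDGFB-WT was 0.023 over gene bodies. Capped to 0 or 1 with a minimum of 20, PDGFB-NLS against Control gave 0.075 for AP-1 genes in microglia-like, -0.018 for chromatin regulators in endothelial-like barcodes and 0.088 for progenitor markers in clusters 1 and 5. In PDGFB-WT against Control, Stat5b was 0.77 in 500 bp windows and Tet3 0.21 per kb of peak. In PDGFB-NLS against Control, 500 bp windows gave 0.71 for Bsn, 0.37 for Stat5b and 0.22 for Parp9, and 2000 bp windows gave -0.33 for Grin1 and -0.076 for Cnfn. Gene bodies gave 0.15 for Bsn and -0.076 for Cnfn, and common regions -0.024 for Cnfn and 0.041 for Uba7. Between the PDGFB libraries, gene bodies gave 0.0051 for Cspg4, 0.13 for Tmsb4x and 0.11 for Ryr3.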

Other observations

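The genes in this part, the OPC-like class at resolution 1.0 and the minimum of 20 were chosen after their values were seen. At that resolution, the OPC-like barcodes of PDGFB-NLS (1318) and PDGFB-WT (1515) differed in 3 of 18 lists, where the all-gene median was 0.06. Hypoxia and glycolysis genes had a median of 0.40 (14 of 16 above 0, percentile 99.74), with the hexokinase gene Hk2 at 1.07 (0.47 to 1.71), Pdk1 at 0.77 (0.29 to 1.28), the glucose transporter gene Slc2a1 at 0.67 (0.15 to 1.22) and Vegfa at -0.60 (-1.26 to 0.07). Replication and cell cycle genes were at 0.23 (19 of 26, percentile 98.07), and OPC markers at -0.16 (7 of 18, percentile 1.02). In the main setting, with a minimum of 100, 0 of 9 lists left the random range and replication and cell cycle genes were at -0.14 (3 of 7 above 0, percentile 15.2). At resolution 0.6 and the minimum of 20, 0 of 19 lists left it, with hypoxia genes at 0.26 (percentile 97.49) just inside, and 1 of 19 did so in regions called in all 3 libraries, hypoxia genes at percentile 98.4.

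In the microglia-like class of PDGFB-WT against Control, the myeloid transcription factor gene Spi1 was at -1.23 (-1.73 to -0.77), and the receptor genes P2ry12 and Csf1r at -0.88 (-1.44 to -0.37) and -0.85 (-1.50 to -0.25). In PDGFB-NLS against Control, Ly86 was at -0.65 (-0.95 to -0.35), the complement gene C1qb at -0.29 (-0.49 to -0.09), Siglech at 0.64 (0.23 to 1.05), Hoxa3 at 0.59 (0.18 to 1.004) and Hoxa4 at 0.67 (0.13 to 1.20). In PDGFB-NLS cluster 1 against Control cluster 5, where the all-gene median was -0.22, Hes1 was at -0.92 (-1.22 to -0.62), the feedback genes Dusp6 and Spry2 at -0.65 (-0.96 to -0.34) and -0.57 (-0.90 to -0.23), and Etv5 and Etv4 at -0.47 (-0.72 to -0.21) and -0.47 (-0.86 to -0.06).

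The unnamed PDGFB-WT clusters had the largest chromosome ratios of any cluster against the rest of its library, 0.66 for chromosome 2 in cluster 4 (bin median -0.01, bin SD 0.80) and 0.40 for chromosome 17 in cluster 5 (bin median -0.02, bin SD 0.46). The OPC-like clusters stood at -0.09 in PDGFB-WT and -0.12 in PDGFB-NLS for chromosome 17, their largest.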
